A study of Homo sapiens with 14 samples.

How the data were processed

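Total RNA of MV4;11 and EOL-1 cells was sequenced in 14 libraries, 2 in each of 7 groups. Per the labels' protocols, cells grew in RPMI medium with serum, doxycycline was given at 1 µg/ml for 4 days, RNA came from a Qiagen RNeasy kit and libraries from a NEBNext Ultra II kit. Samples were grouped by their titles. The columns of the tables carry shorter names than the titles and were matched to samples by inference, from the comparison each table holds, the target, the guide number and the replicate number. The guide numbers are 1 and 5, and the sgRNA in EOL-1 is called by its target only. No sample was left unassigned.

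Each of 3 tables held one comparison: shEZH2 with EV, sgcMyc with sgEV, and sgEZH2 with sgEV in EOL-1. Per the file headers, every library has a raw column and a normalised column. The raw columns hold estimated counts per gene (expected counts that need not be whole), as deposited by the authors, and the submitters' processing notes name RSEM, DESeq and the genome build hg19. The normalised columns hold log2 values made by the authors, who do not state the method in the sources used here. Versions, the aligner, the gene annotation and any gene filter are not given in the sources used here. The reference genome at hand was of another build, so no coordinates are printed, and genes are named by the symbols in the tables. Strand use in counting is not stated either, so overlapping and antisense genes cannot be separated.

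The tables held 15081 rows for each MV4;11 comparison and 15031 for EOL-1, with 13720 gene rows in all 3. Both MV4;11 tables list 56 spike-in rows, which took 1.06 to 1.30% of the counts and stayed out of library sizes and tests. A calendar date stands in place of a gene symbol in 18 rows of each table, which were tested and not named. Gene counts per library came to 13313052 to 16274568 in MV4;11 and 24574102 to 30256823 in EOL-1. Replicate libraries differed by more than sampling noise in every group (chi-square per degree of freedom 1.47 to 5.47 over genes with at least 20 counts), so none was counted as a copy. Lowest was 1.47 in the sgEV libraries of MV4;11, and highest was 5.47 with guide 5. The edgeR biological coefficient of variation was 0.0352 for shEZH2, 0.0422 for sgcMyc and 0.0257 for EOL-1.

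Estimated counts were rounded to whole numbers. Genes passed filterByExpr of edgeR, libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit with robust empirical Bayes, glmQLFTest) was run within each table, with Benjamini-Hochberg adjustment and a threshold of 0.05. The sgcMyc table was fitted with 3 groups, and the main contrast was the mean of both guides minus sgEV. Each guide and the difference of the guides came from the same fit. CPM values are scaled by TMM. The difference of EZH2 effects between the lines was an interaction contrast in one edgeR fit over both tables, which the submitters' processing notes give the same tools. Overlaps of called genes were tested with Fisher's exact test per direction on the genes tested in both comparisons, beside the overlap of independent lists. That test counts genes as independent, which co-regulated genes are not, so its p-values do not measure the spread between libraries. Simulated unchanged groups against the shared sgEV libraries were drawn 20 times for the agreement of the guides.

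Before the data were examined, 33 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. Lists were tested with camera of limma (preset correlation of 0.01 between genes, two-sided, adjusted over the lists of a comparison) where at least 5 members were tested, and again with an estimated correlation and with fry. The targeted gene was left out of its own lists. With an estimated correlation, none of the list calls in the 3 main comparisons held. Some lists share members, such as RRP12, UTP20, RCL1 and MPHOSPH10 in the lists of MYC-activated genes and of ribosome assembly. The named genes are EZH2 and MYC in every comparison, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change, up to 4 members of each described list with the smallest p, and the 8 genes per direction with the largest smaller change among those called the same way in 2 comparisons. Some members of lists that meet this rule are not reported here. For the largest changes, a mean of at least 50 normalised counts in the higher group and no overlap between the groups' libraries were asked, and symbols of clones, antisense and small RNAs were passed over. A gene at 0 in all libraries of a group is given as a lower bound against 3 counts over the group, and ratios on 1 to 3 counts carry a 95% counting interval.

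Genes with near-identical copies are uncertain, because the authors' counting could split reads between copies. Among those named, these are the HLA genes, ribosomal protein genes with processed pseudogenes, mitochondrial genes with nuclear copies, histones, FCGR1A, TPSB2, CBS, KRT8 and ULBP1.

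The tests were tried on simulated data made from the real means and library sizes, with 100 genes changed 1.5-fold and 100 changed 2-fold. All genes of a simulation had the same dispersion, unlike real genes, so recovery and false calls may look better than in the data. For the interaction the coefficient of variation was set to a fixed value below that of shEZH2. For shEZH2, 93 of 100 were recovered at 1.5-fold and 100 at 2-fold, with 9 false calls (4.09% of calls, 13351 genes). For EOL-1 these were 94, 100 and 16 (6.99%, 13660 genes), and for sgcMyc 96, 100 and 10 (4.42%, 13694 genes). The interaction test recovered 94 of 100 at 2-fold with 3 false calls over 13543 genes.

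The alternatives were limma with trend on log2(value + 1), DESeq2, size factors of the DESeq2 kind (RLE), no filter on low counts, a mean of at least 50 counts, no robust step, an absolute log2 fold change of at least 1, adjusted p under 0.01, each library left out in turn, the replicate number as a block, and the 4 sgcMyc libraries as 1 group. Added after seeing the data were limma on the authors' log2 values, scaling to the spike-in rows and the alternatives of the difference between the lines. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. With 2 libraries per group neither regrouping of the samples nor a test for single extreme libraries was run.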

Results

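Transcript levels were measured by RNA-seq in 2 human leukaemia cell lines. MV4;11 is a myelomonocytic line that carries the KMT2A-AFF1 fusion, and EOL-1 is a line from an eosinophilic leukaemia. The 14 libraries fall into 7 groups of 2. In MV4;11, EZH2 depletion (shEZH2) was set beside the control labelled EV, and the knockout of cMyc with sgRNA 1 or sgRNA 5 (sgcMyc) was set beside the control labelled sgEV. In EOL-1, EZH2 depletion (sgEZH2) was set beside its own sgEV control. EZH2 is the histone H3 lysine methyltransferase of Polycomb repressive complex PRC2, and MYC (cMyc) is a transcription factor that drives growth genes. Each library held 15034533 to 16274568 counts in the EV and shEZH2 libraries, 13313052 to 15043385 in the sgEV and sgcMyc libraries and 24574102 to 30256823 in the EOL-1 libraries. All values below rest on n = 2 libraries per group, log2 fold changes stand as value ± SE, and mean levels in CPM (counts scaled to a common library size) stand as value ± SD. Each SE is implied by the F statistic of edgeR's test, as the absolute log2 fold change divided by the square root of F. Adjusted p-values for genes come from edgeR's quasi-likelihood test, and those for gene lists from limma's camera test. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

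The targeted transcripts were examined first. EZH2 fell from 74.5 ± 1.76 to 9.72 ± 0.04 CPM with shEZH2 in MV4;11, to 13.1% of the control (log2 fold change -2.94 ± 0.07, adjusted p = 2.8e-09). In EOL-1 with sgEZH2 it fell from 70.5 ± 0.20 to 26.9 ± 1.14 CPM, to 38.3% of the control (-1.39 ± 0.05, adjusted p = 3.2e-13). MYC did not fall in the libraries labelled sgcMyc. It rose from 659 ± 1.93 CPM in sgEV to 869 ± 4.15 CPM with guide 1 and 820 ± 2.53 CPM with guide 5 (0.36 ± 0.04, adjusted p = 1.3e-05). A cut by Cas9 alters the coding sequence and need not lower the transcript, so the MYC transcript checks neither the label nor the knockout, and the same holds for EZH2 with an sgRNA. Every direction given below for cMyc therefore rests on the labels, and the libraries are called libraries labelled sgcMyc. MYC rose slightly with shEZH2, from 578 ± 7.14 to 685 ± 5.45 CPM (0.25 ± 0.04, adjusted p = 5.7e-04), and the change in EOL-1 did not pass the test (-0.04 ± 0.03, adjusted p = 0.354). EZH2 was lower in the libraries labelled sgcMyc by a small margin (-0.19 ± 0.06, adjusted p = 0.0183), and with guide 5 alone it did not pass (-0.16, adjusted p = 0.0766). The call for both guides was lost without sgEV library 1 (adjusted p = 0.228), sgEV library 2 (0.0546), guide 1 library 1 (0.0604) or guide 1 library 2 (0.0592), with DESeq2 (0.164) and with scaling to the spike-in RNAs (0.546).

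**Figure D1:**
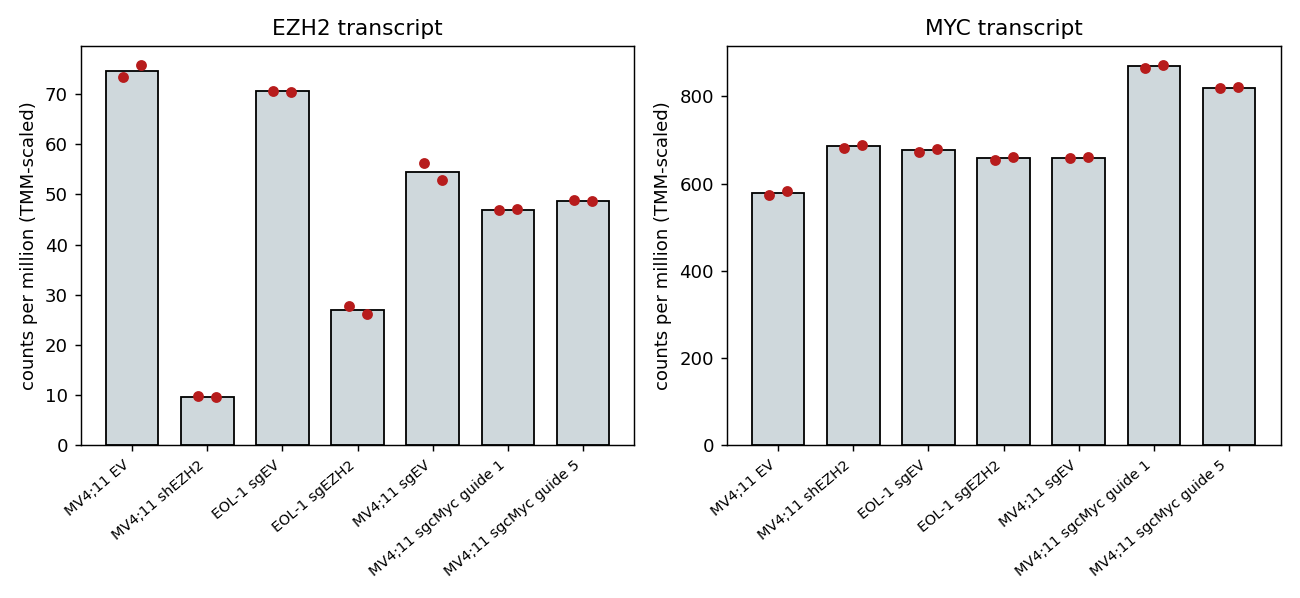
Level of EZH2 and of MYC in CPM (vertical axis, from 0) in each of the 7 groups, where bars are group means and points are the 2 libraries. EZH2 stood at 9.72 CPM in shEZH2 and 26.9 CPM in sgEZH2, and MYC was higher in both sgcMyc groups than in sgEV.

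EZH2 depletion in MV4;11 addressed which transcripts depend on EZH2 in this line. Genes of cholesterol synthesis fell with shEZH2: 19 of 23 tested members were lower and 0 higher (0 higher and 20 lower when adjusted over the list alone), with a median log2 fold change of -0.41. They included CYP51A1, an enzyme of sterol synthesis (-1.05), and SREBF2, the transcription factor that drives the pathway (-0.60). Genes of mitosis fell in 26 of 43 cases with 0 higher (0 and 29 over the list alone, median -0.19), among them the anaphase activator CDC20 (-0.93), the cytokinesis factor ANLN (-0.59), BIRC5 (-0.43) and cyclin CCNB1 (-0.33). Of 46 DNA replication genes 14 fell and 0 rose (0 and 16 over the list alone, median -0.10), including UHRF1 (-0.42) and MCM3 (-0.43). Targets of p53 moved the other way, with 19 of 33 higher and 0 lower (22 and 0 over the list alone, median 0.29). CYFIP2 (3.36 ± 0.17), the stress-response gene SESN1 (1.12), TRIM22 (0.72) and the ribonucleotide reductase subunit RRM2B (0.65) led that list, while CDKN1A, which encodes the cell cycle inhibitor p21, did not pass the test (0.05, adjusted p = 0.580). Camera gave adjusted p = 1.3e-12 for cholesterol synthesis, 6.2e-10 for mitosis, 8.5e-04 for DNA replication and 1.6e-08 for p53 targets. With an estimated correlation between genes these became adjusted p = 0.194, 0.194, 0.293 and 0.194.

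Interferon-stimulated genes were lower with shEZH2 in 16 of 32 cases and higher in 2 (2 and 17 when adjusted over the list alone, median -0.51, adjusted p = 4.5e-05, and adjusted p = 0.293 with an estimated correlation). The antiviral factor BST2 (-0.59), XAF1 (-0.64) and PARP14 (-0.81) fell and TRIM22 rose. In the amino acid and endoplasmic reticulum (ER) stress list 15 of 29 members fell and 2 rose (3 and 16 over the list alone, median -0.20, adjusted p = 5.3e-04, and adjusted p = 0.293 with an estimated correlation). PHGDH (-0.95) and PSAT1 (-0.84), which act in serine synthesis, the asparagine synthetase ASNS (-0.92) and TRIB3 (-0.84) were among them. Ribosomal protein genes rose by small amounts, with 48 of 78 higher and 0 lower (59 and 0 over the list alone, median 0.15, adjusted p = 1.3e-12, and adjusted p = 0.619 with an estimated correlation). RPL23 (0.34), RPL5 (0.30) and RPL15 (0.26) led them. All 13 genes of the mitochondrial genome rose (13 and 0 over the list alone, median 0.39, adjusted p = 1.9e-11, and adjusted p = 0.293 with an estimated correlation), for example MT-CYB (0.47) and MT-ND2 (0.46). The mitochondrial share of all counts was 2.18% and 2.22% in the EV libraries and 2.79% and 2.80% in the shEZH2 libraries. It thus differed between the same libraries as the gene lists that changed in this comparison.

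Among early myeloid granule genes 8 of 14 rose and 2 fell (8 and 3 over the list alone, median 0.21). MS4A3 (0.94), IGLL1 (0.59) and PRTN3 (0.24) were among those that rose, and myeloperoxidase MPO fell (-0.51). The set call (adjusted p = 0.0330) became adjusted p = 0.619 with an estimated correlation and was lost without EV library 1 (0.0535) or shEZH2 library 2 (0.0511). Of 49 genes of rRNA synthesis and ribosome assembly, 10 rose and 1 fell (9 and 1 over the list alone, median 0.05), led by UTP20 (0.34, not called with spike-in scaling, adjusted p = 0.0993). That set call (adjusted p = 0.0448) became adjusted p = 0.357 with an estimated correlation. It was also lost without EV library 1 (0.0889), shEZH2 library 1 (0.0674) or shEZH2 library 2 (0.0659), with a mean of at least 50 counts (0.0621), with limma on the authors' log2 values (0.0503) and with spike-in scaling (0.289). Immediate early genes fell in 6 of 15 cases and rose in 1 (1 and 6 over the list alone, median -0.21), including JUND (-0.37) and JUNB (-0.40). Their call (adjusted p = 0.0336) became adjusted p = 0.619 with an estimated correlation and was lost without EV library 2 (0.0627) or shEZH2 library 1 (0.0912) and with spike-in scaling (0.0501).

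Myeloid differentiation genes went both ways with shEZH2 and did not pass as a set (7 higher and 14 lower of 28, 7 and 15 over the list alone, adjusted p = 0.0987). The lysozyme gene LYZ rose (1.37 ± 0.05, to 502 from 194 CPM) and so did the transcription factor IRF8 (0.55), whereas the Fc receptor FCGR1A (-1.59) and the lysosomal protease CTSB (-0.94) fell. In the HOXA-MEIS1 leukaemia programme 4 of 16 rose and 4 fell (the same numbers over the list alone, adjusted p = 0.235), with MEF2C (-0.85), the receptor kinase FLT3 (-0.43) and SATB1 (-0.31) lower. Of the 10 PRC2 subunits and partners tested besides EZH2, JARID2 rose (0.84), 1 fell and 8 did not pass (the same over the list alone, adjusted p = 0.966). Of 56 MYC-activated genes 12 rose and 7 fell (13 and 7 over the list alone, adjusted p = 0.168), and the list's mean changed sign with spike-in scaling, from 0.04 to -0.01. BCL2, which encodes an inhibitor of apoptosis, rose (0.55), within a BCL2 family of 13 with 5 higher and 4 lower (5 and 5 over the list alone, adjusted p = 0.966). In the MHC class II pathway 3 of 11 were higher and 3 lower (3 and 4 over the list alone, adjusted p = 0.447). HLA-DRB1 fell (-1.65) and HLA-DRA rose (0.86), a call lost when 1 of the libraries was left out.

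The other lists did not pass in this comparison either. The members higher and lower were 3 and 2 of 11 for the MYC-MAX network (4 and 2 over the list alone), 5 and 10 of 20 aminoacyl-tRNA synthetases (6 and 10), 8 and 8 of 27 nucleotide synthesis genes (10 and 8) and 6 and 6 of 21 glycolysis genes (7 and 6). They were 4 and 4 of 45 nuclear-encoded oxidative phosphorylation genes (2 and 1), 0 and 4 of 8 CDK inhibitors (0 and 4), 3 and 1 of 18 developmental transcription factors (3 and 1) and 3 and 5 of 18 genes of the MHC class I pathway (3 and 6). They were 1 and 1 of 12 histone acetyltransferases including EP300 and CREBBP (1 and 1), 3 and 1 of 19 PRC1 subunits (3 and 1) and 0 and 0 of 9 replication-dependent histones (0 and 0). Adjusted p in these sets ran from 0.0698 for the CDK inhibitors to 0.966. Of a longer list of developmental transcription factors, only 22 had rows in each MV4;11 comparison. For shEZH2 5 of these stood above 10 CPM. Listed members without rows could not be tested, so the values do not speak for them. Median and mean differed in sign for PRC2 (-0.02 and 0.05), the MYC-MAX network (-0.02 and 0.14), nucleotide synthesis (0.03 and -0.01), developmental transcription factors (-0.05 and 0.35) and MHC class I (0.03 and -0.12). For the BCL2 family camera pointed up while the median was -0.08 and the mean -0.02. The means of glycolysis genes and of histone acetyltransferases changed sign with spike-in scaling. Markers of other cell types had too few tested members for a set test. The T and NK cell marker NKG7 fell (-0.45, 1 of 2 tested), the B cell marker CD79A rose (1 of 3), the erythroid and megakaryocyte markers EPOR (-0.68) and GP9 fell (2 of 3), the mast cell marker TPSB2 fell (1 of 1) and the epithelial marker KRT8 fell (-0.78, 1 of 2). Over each list alone the numbers were the same except for B cells (1 higher and 1 lower). CD79A, GP9 and TPSB2 had so few counts that no fold is given. The calls of CD79A (adjusted p = 0.335), TPSB2 (0.0593) and KRT8 (0.0586) were lost with DESeq2. That of CD79A was also lost without EV library 1 (0.138), shEZH2 library 1 (0.0720) or shEZH2 library 2 (0.250), with spike-in scaling (0.0784) and without the robust step (0.0515).

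The largest rises with shEZH2 were those of PON2 (paraoxonase 2), which had 191 counts against 0 in the control and was at least 62.0-fold higher against a floor of 3 counts over the group, the kinase HUNK (3.70 ± 0.37, adjusted p = 2.9e-05), NT5C3B (3.56), the palmitoyltransferase ZDHHC2 (3.55), UGT3A2 (3.36), CYFIP2, the potassium channel KCNK10 (3.22) and HAPLN4 (3.08 ± 0.11). The largest falls were those of MYBPH (-4.11 ± 0.23, adjusted p = 4.8e-07), MPV17L (-3.75), the transcription factor CREB5 (-3.49), ZNF71 (-3.37), LGALS3BP (-3.32), CHI3L1 (-3.27 ± 0.26), TMEM246 (-2.95) and FCER2, the low-affinity IgE receptor CD23 (-2.68 ± 0.12, adjusted p = 7.2e-08). Of 13591 genes tested 1824 were higher and 1934 lower, and 244 and 290 of these changed at least 2-fold. Without shEZH2 library 1 the number higher was 1186, and DESeq2 called 905 higher and 939 lower. With spike-in scaling 36.4% of called genes were higher (805 genes), against 48.5% with the scaling used here.

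In EOL-1, the comparison of sgEZH2 with sgEV addressed the same question in another line. Myeloid differentiation genes rose in 27 of 31 cases and fell in 2 (27 and 2 when adjusted over the list alone, median 0.76). LYZ, a monocyte and granulocyte enzyme, rose to 1640 from 198 CPM (3.05 ± 0.03), the macrophage growth factor receptor CSF1R rose by 3.76 ± 0.10, the scavenger receptor CD36 by 2.69 and the calcium-binding protein S100A9 by 1.67. Early myeloid granule genes rose in 11 of 13 cases and fell in 2 (11 and 2 over the list alone, median 0.92), including the neutrophil protease PRTN3 (3.09), MS4A3 (3.07), myeloperoxidase MPO (1.70) and CFD (0.95). In the MHC class II pathway 14 of 16 members rose and 0 fell (14 and 0 over the list alone, median 1.39), among them the antigen-presenting chains HLA-DPA1 (4.79 ± 0.13), HLA-DRB1 (1.71) and HLA-DRA (1.28). In the MHC class I pathway 15 of 18 rose and 0 fell (16 and 0 over the list alone, median 0.45), including HLA-B (1.27) and HLA-C (1.15). Camera gave adjusted p = 2.5e-18 for myeloid differentiation, 6.4e-09 for granule genes, 3.4e-14 for MHC class II and 1.3e-12 for MHC class I. With an estimated correlation these became adjusted p = 0.175, 0.175, 0.175 and 0.190. The HLA genes are close paralogs whose reads the authors' counting could split, so their single values are uncertain.

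Interferon-stimulated genes rose in EOL-1 in 12 of 31 cases with 0 lower (13 and 0 over the list alone, median 0.24, adjusted p = 4.2e-06, and adjusted p = 0.175 with an estimated correlation). DDX60 (1.84), GBP2 (1.01) and LGALS3BP (1.49) were among them. Of 33 p53 targets 18 rose and 2 fell (19 and 2 over the list alone, median 0.18, adjusted p = 8.9e-06, and adjusted p = 0.175 with an estimated correlation), with CDKN1A (1.65 ± 0.04, adjusted p = 1.5e-15), SESN1 (0.79), ZMAT3 (0.68) and GADD45A (0.84). Ribosomal protein genes rose in 26 of 78 cases with 0 lower (30 and 0 over the list alone, median 0.08, adjusted p = 3.5e-07, and adjusted p = 0.638 with an estimated correlation), including RPL23 (0.22). Of 13 genes of the mitochondrial genome 8 rose and 0 fell (12 and 0 over the list alone, median 0.12, adjusted p = 1.8e-04, and adjusted p = 0.514 with an estimated correlation), including MT-ND2 (0.29). The mitochondrial share was 1.06% and 1.05% in sgEV and 1.14% in each sgEZH2 library. It too differed between the same libraries as the lists that changed in this comparison.

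Several lists fell in EOL-1 by small amounts. Of 46 DNA replication genes 24 fell and 1 rose (1 and 26 over the list alone, median -0.11, adjusted p = 8.9e-09), including the polymerase subunit POLE (-0.34), CDC6 (-0.31), CDT1 (-0.26) and MCM2 (-0.21). Of 43 mitosis genes 25 fell and 0 rose (1 and 27 over the list alone, median -0.15, adjusted p = 6.8e-09), including CENPF (-0.39), ESPL1 (-0.33), FOXM1 (-0.32) and BUB3 (-0.22). Nucleotide synthesis (1 higher and 10 lower of 27, 2 and 12 over the list alone, adjusted p = 2.5e-04) included SHMT1 (-0.34) and CAD (-0.23). Aminoacyl-tRNA synthetases (1 higher and 11 lower of 20, 1 and 12 over the list alone, adjusted p = 3.4e-04) included MARS (-0.23), GARS (-0.22) and YARS (-0.21). With an estimated correlation these lists gave adjusted p = 0.175, 0.211, 0.190 and 0.204. The amino acid and ER stress list had 3 of 28 higher and 13 lower (5 and 15 over the list alone, adjusted p = 0.00780, and adjusted p = 0.211 with an estimated correlation). PSAT1 (-0.45) and the amino acid transporter SLC7A5 (-0.24) fell, while HERPUD1 (0.65) and the ER chaperone HSPA5 (0.32) rose. Of the 10 PRC2 subunits and partners besides EZH2, 5 fell and 0 rose (1 and 6 over the list alone, adjusted p = 0.00559, and adjusted p = 0.272 with an estimated correlation), SUZ12 by -0.19. MYC-activated genes were lower in 13 of 56 cases and higher in 3 (3 and 16 over the list alone, median -0.02), including UNG (-0.24) and MCM4 (-0.20). Their set call (adjusted p = 0.0268) became adjusted p = 0.514 with an estimated correlation and was lost without sgEV library 2 (0.0738), without sgEZH2 library 1 (0.0995) and with a mean of at least 50 counts (0.0788).

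The other lists did not pass in EOL-1. In the HOXA-MEIS1 programme 7 of 20 were higher and 2 lower (8 and 3 over the list alone, adjusted p = 0.0677), with MEF2C (1.54), SATB1 (1.22) and the PRC1 subunit BMI1 (0.82) up and the kinase CDK6 (-0.37) down. Cholesterol synthesis had 5 of 23 higher and 3 lower (5 and 3 over the list alone, adjusted p = 0.504). The members higher and lower were 2 and 0 of 11 for the MYC-MAX network (2 and 0 over the list alone), 4 and 5 of 48 for rRNA synthesis and ribosome assembly (3 and 5), 2 and 2 of 21 for glycolysis (2 and 2) and 7 and 3 of 45 for oxidative phosphorylation (7 and 3). They were 1 and 2 of 6 CDK inhibitors (1 and 2), 6 and 4 of 24 developmental transcription factors (7 and 4), 3 and 3 of 13 in the BCL2 family (4 and 3) and 1 and 3 of 12 histone acetyltransferases (1 and 3). They were 6 and 3 of 19 PRC1 subunits (7 and 4), 1 and 5 of 15 immediate early genes (2 and 6) and 1 and 0 of 9 replication-dependent histones (0 and 0). Adjusted p ran from 0.0677 to 0.774. Only 26 of the listed developmental transcription factors had rows in EOL-1, and the others could not be tested. For the MYC-MAX network the median was -0.02 and the mean 0.06, and that mean changed sign in the log2 values the authors deposited. Of other cell type markers, the B cell genes CD79A (1.08), IGHM (0.42) and FCRLA rose (3 of 4), NKG7 (1 of 2) and EPOR (-0.52, 1 of 2) fell, and 0 of 2 eosinophil, basophil and mast cell markers and 0 of 1 fibroblast and epithelial marker passed. Over each list alone the numbers were 4 and 0 for B cells, 0 and 2 for T and NK cells and 1 and 1 for erythroid and megakaryocyte genes. The calls of IGHM (adjusted p = 0.0708) and FCRLA (0.114) were lost with DESeq2, and that of FCRLA also without sgEV library 1 (0.0533) or sgEZH2 library 2 (0.0576).

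Counts in the control were few for some of the genes with the largest rises in EOL-1. UBE2E2, a ubiquitin-conjugating enzyme, had 152 counts against 1, a ratio of 173 (95% counting interval 30.5 to 6866), the phosphatase PTPN13 256 against 2 (145, 39.9 to 1207) and the RNA-binding protein IGF2BP2 116 against 1 (132, 23.2 to 5250). Such intervals cover counting error only. The growth factor IGF1 rose by 4.96 ± 0.47 (adjusted p = 2.0e-07), HLA-DPA1 as given above (adjusted p = 4.5e-15), the ubiquitin ligase NEDD4 by 4.38, the desmosomal cadherin DSC2 by 4.30 and SPRED1, an inhibitor of Ras signalling, by 4.22. The largest falls were those of SLITRK5 (-2.56), the cytokine IL32 (-2.52 ± 0.07, adjusted p = 3.6e-15), ARAP2 (-1.70), TMEM110-MUSTN1 (-1.56), ANXA2R (-1.35), PHACTR3 (-1.32), CHURC1-FNTB (-1.3) and the G protein subunit GNG4 (-1.12). The pair of joined symbols name readthrough transcripts that share exons with their parent genes and are uncertain. CHURC1-FNTB was no longer called without sgEV library 1 (adjusted p = 0.466), sgEZH2 library 1 (0.198) or sgEZH2 library 2 (0.136), or with DESeq2 (0.0729) or limma on the authors' log2 values (0.0738), and TMEM110-MUSTN1 was not called by limma on log2 counts (0.0563). Of 13890 genes tested 2099 were higher and 1639 lower, and 466 and 52 of these changed at least 2-fold. The number lower was 1061 without sgEV library 1 and 1020 without sgEV library 2, and DESeq2 called 1122 higher and 748 lower.

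**Figure D2:**
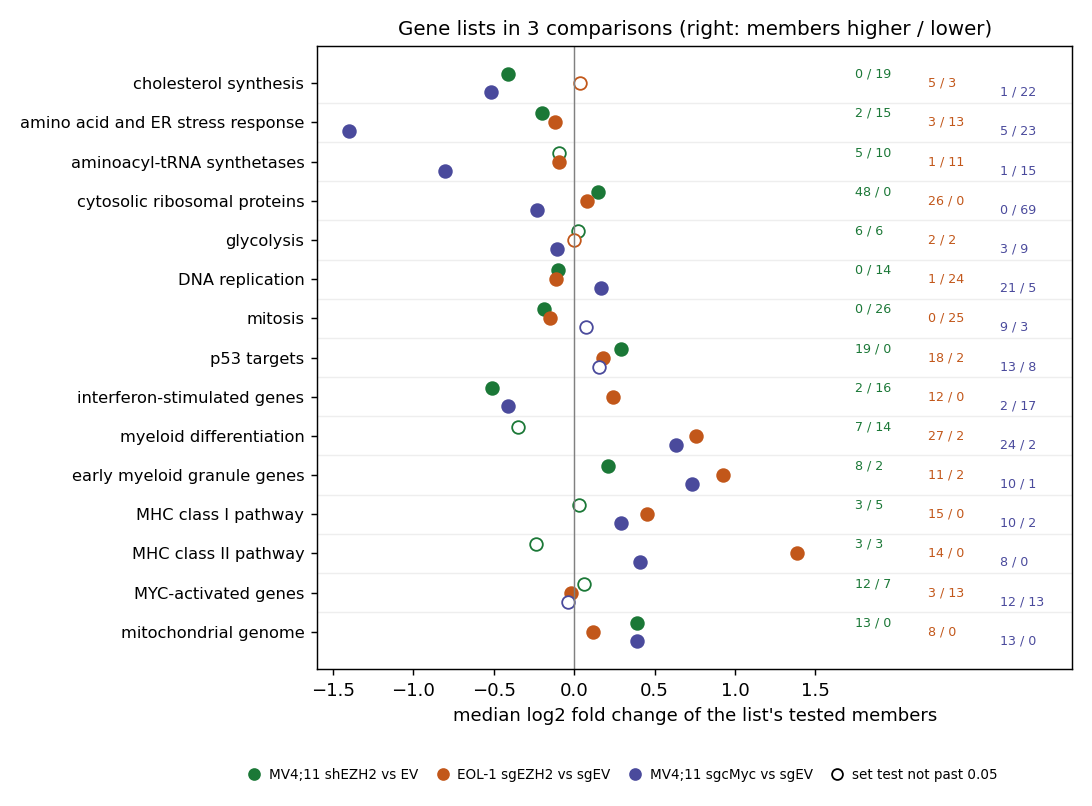
Median log2 fold change (horizontal axis) of the tested members of 15 gene lists in shEZH2 against EV, sgEZH2 against sgEV and sgcMyc (mean of both guides) against sgEV, with filled points where camera's adjusted p was under 0.05 and, at the right, the numbers of members higher and lower. Myeloid and MHC lists lie to the right for EOL-1, the amino acid list lies at -1.40 for sgcMyc, and the mean of the MYC-activated list changed sign with spike-in scaling in both MV4;11 comparisons, as did glycolysis in shEZH2 and p53 targets in sgcMyc.

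For cMyc the comparison asked which transcripts differ when MYC is targeted with either of 2 sgRNAs. In the libraries labelled sgcMyc, genes of the amino acid and ER stress response fell in 23 of 29 cases and rose in 5 (5 and 23 when adjusted over the list alone, median -1.40, adjusted p = 5.0e-15). PHGDH, the first enzyme of serine synthesis, fell to 32.4 from 418 CPM (-3.69 ± 0.05), and PSAT1 (-2.74), ASNS (-3.35) and DDIT4 (-3.13) fell as well. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, fell in 15 of 20 cases and rose in 1 (1 and 17 over the list alone, median -0.80, adjusted p = 2.4e-12), including GARS (-1.64), CARS (-1.56), WARS (-1.38) and AARS (-1.31). Cholesterol synthesis fell in 22 of 23 cases and rose in 1 (1 and 22 over the list alone, median -0.51, adjusted p = 2.5e-14), including HMGCS1 (-1.02), DHCR7 (-0.93) and MSMO1 (-0.84). Ribosomal protein genes fell in 69 of 78 cases with 0 higher (0 and 73 over the list alone, median -0.23, adjusted p = 3.1e-15), including RPL12 (-0.38) and RPL36 (-0.33). With an estimated correlation these lists gave adjusted p = 0.0822, 0.0668, 0.0668 and 0.532. Scaling to the spike-in RNAs moved the median of all genes in this comparison from 0.00 to 0.11, so the folds here are relative to the other genes.

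Myeloid genes rose in the libraries labelled sgcMyc, with 24 of 32 members of the differentiation list higher and 2 lower (24 and 2 over the list alone, median 0.63, adjusted p = 1.6e-12, and adjusted p = 0.0668 with an estimated correlation). LYZ rose to 3576 from 158 CPM (4.50 ± 0.05), CD36 by 1.78 and the lysosomal glycoprotein CD68 by 1.32. S100A9 had 728 counts against 2, a ratio of 169 (95% counting interval 46.6 to 1398). Granule genes rose in 10 of 14 cases and fell in 1 (10 and 1 over the list alone, median 0.73, adjusted p = 1.3e-06, and adjusted p = 0.175 with an estimated correlation), with MS4A3 (2.46), RNASE2 (1.60) and PRTN3 (1.22) higher and CST7 (-1.89) lower. In MHC class I 10 of 18 rose and 2 fell (11 and 2 over the list alone, median 0.29, adjusted p = 5.7e-04, and adjusted p = 0.373 with an estimated correlation), including HLA-B (0.79), HLA-C (0.73), CALR (0.60) and B2M (0.60). In MHC class II 8 of 13 rose and 0 fell (8 and 0 over the list alone, median 0.41, adjusted p = 0.00331, and adjusted p = 0.286 with an estimated correlation), including HLA-DRA (1.52), HLA-DQB1 (1.2) and CD74 (0.46). Interferon-stimulated genes fell in 17 of 35 cases and rose in 2 (2 and 18 over the list alone, median -0.41), with IFIT2 (-1.96), OAS2 (-1.45), XAF1 (-1.12) and LGALS3BP (-0.92) lower. That call (adjusted p = 0.00111) became adjusted p = 0.150 with an estimated correlation and 0.0573 with a mean of at least 50 counts.

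Oxidative phosphorylation genes encoded in the nucleus rose in 24 of 45 cases and fell in 1 (26 and 1 over the list alone, median 0.18, adjusted p = 7.2e-05, and adjusted p = 0.649 with an estimated correlation), including NDUFA4 (0.48) and NDUFB10 (0.33). All 13 genes of the mitochondrial genome rose (13 and 0 over the list alone, median 0.39, adjusted p = 2.6e-09, and adjusted p = 0.248 with an estimated correlation), including MT-ND3 (0.57) and MT-CO1 (0.54). The mitochondrial share of counts was 2.47% and 2.41% in sgEV, 3.18% and 3.14% with guide 1 and 3.44% and 3.16% with guide 5. Its change lay between the same libraries as that of the lists that moved in this comparison. DNA replication genes rose in 21 of 46 cases and fell in 5 (23 and 5 over the list alone, median 0.16, adjusted p = 6.7e-04, and adjusted p = 0.261 with an estimated correlation), with FEN1 (0.47), PCNA (0.44) and RPA1 (0.37) up and CDT1 (-0.88) down. Glycolysis genes fell in 9 of 21 cases and rose in 3 (3 and 11 over the list alone, median -0.11), including the glucose transporter SLC2A3 (-1.2), ENO2 (-1.16), ALDOC (-1.03) and PFKP (-0.70). Their call (adjusted p = 0.00630) became adjusted p = 0.493 with an estimated correlation and 0.0945 with spike-in scaling. Genes of rRNA synthesis and ribosome assembly fell in 17 of 49 cases and rose in 4 (4 and 18 over the list alone, adjusted p = 0.00559, and adjusted p = 0.373 with an estimated correlation), but the list's mean changed sign with spike-in scaling, from -0.10 to 0.01 (adjusted p = 0.235). NOB1 (-0.55) and WDR12 (-0.44) were among those that fell.

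The 56 MYC-activated genes, a list fixed from textbook knowledge of MYC targets, did not pass as a set in the libraries labelled sgcMyc. Of these 12 rose and 13 fell (13 and 14 over the list alone, adjusted p = 0.588), with PUS1 (-0.88), TCOF1 (-0.62), SORD (-0.49) and TMEM97 (-0.44) lower, and the mean changed sign with spike-in scaling, from -0.04 to 0.08. Nucleotide synthesis had 6 of 27 higher and 8 lower (6 and 8 over the list alone, adjusted p = 0.813), with the mitochondrial folate enzymes MTHFD2 (-1.40) and SHMT2 (-1.12) down. Of 33 p53 targets 13 rose and 8 fell (14 and 8 over the list alone, adjusted p = 0.40), SESN2 by -1.73 and PMAIP1 by -1.26, while CDKN1A did not pass (-0.09). Of 43 mitosis genes 9 rose and 3 fell (9 and 3 over the list alone, adjusted p = 0.0631, and 0.0320 with spike-in scaling). In the HOXA-MEIS1 programme 2 of 16 rose and 6 fell (3 and 7 over the list alone, adjusted p = 0.282), FLT3 by -0.40. The members higher and lower were 3 and 4 of 11 for PRC2 (3 and 4 over the list alone), 3 and 4 of 10 for the MYC-MAX network besides MYC (3 and 4), 2 and 4 of 8 CDK inhibitors (2 and 5), 3 and 4 of 17 developmental transcription factors (3 and 4) and 5 and 3 of 13 in the BCL2 family (6 and 4). They were 1 and 1 of 12 histone acetyltransferases (1 and 1), 4 and 2 of 19 PRC1 subunits (3 and 2), 6 and 8 of 17 immediate early genes (6 and 8) and 2 and 0 of 10 replication-dependent histones (2 and 0). Adjusted p in these sets ran from 0.114 to 0.964. Median and mean differed in sign for nucleotide synthesis (0.01 and -0.06), p53 targets (0.15 and -0.01), the BCL2 family (0.15 and -0.06), the MYC-MAX network (-0.02 and 0.04) and histone acetyltransferases (-0.03 and 0.02), and for PRC1 the mean lay at 0. With spike-in scaling the means of nucleotide synthesis, p53 targets, HOXA-MEIS1, PRC2, developmental transcription factors, the BCL2 family and PRC1 changed sign. Of other cell type markers, TRAC (-2.56, 1 of 2), GATA2 (-1.29, 1 of 2) and KRT8 (-1.08, 1 of 1) fell, and 0 of 4 B cell and 0 of 4 erythroid and megakaryocyte markers passed, with the same numbers over each list alone. The call of KRT8 was lost without sgEV library 1 (adjusted p = 0.0749) and with DESeq2 (0.0535).

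The largest rises in the libraries labelled sgcMyc were those of S100A9, CRISPLD2 (4.90 ± 0.14, adjusted p = 4.6e-11), S100A8 (4.65), LYZ (adjusted p = 3.8e-14), the bile acid transporter SLC10A2 (4.18), FAM198B (3.98), the myeloid nuclear antigen MNDA (3.76) and CES1 (3.59). The largest falls were those of the NKG2D ligand ULBP1 (-4.17), the glycine transporter SLC6A9 (-3.93), INHBE (-3.89), PHGDH (adjusted p = 4.6e-14), ADM2 (-3.68), the cystathionine synthase CBS (-3.66), the angiopoietin ANGPT1 (-3.64) and CHAC1 (-3.42). Of 13948 genes tested 2590 were higher and 2613 lower, and 261 and 401 of these changed at least 2-fold. The number higher was 1427 without sgEV library 1 and 1511 without sgEV library 2, the number lower was 1508 and 1502, and DESeq2 called 1635 higher and 1584 lower. With spike-in scaling 72.8% of called genes were higher, with 1169 lower, against 49.8% with the scaling used here. The spike-in share was 1.22% and 1.24% in sgEV, 1.15% and 1.18% with guide 1 and 1.06% and 1.18% with guide 5. The guide 5 libraries thus differed from each other about as much as the groups did. Changes seen only with this scaling are uncertain.

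**Figure D3:**
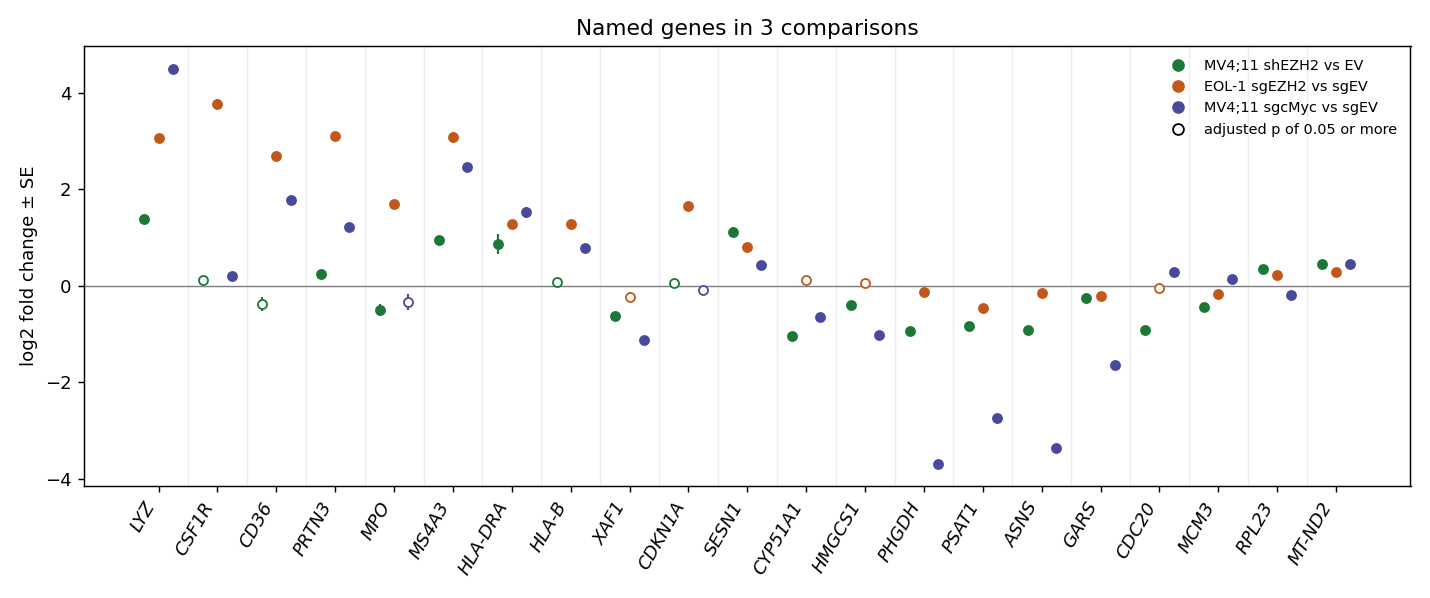
Log2 fold change (vertical axis, points with SE bars) of 21 named genes in shEZH2 against EV, sgEZH2 against sgEV and sgcMyc (mean of both guides) against sgEV, filled where edgeR's adjusted p was under 0.05. LYZ rose in all 3 comparisons (1.37, 3.05 and 4.50), and PHGDH was lowest in sgcMyc (-3.69).

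The guides were also compared with each other. Guide 1 called 4488 genes and guide 5 called 4354, and MYC rose with each (0.40 and 0.32). Across 13948 genes the log2 fold changes of the guides had a Pearson correlation of 0.761, where genes are not independent replicates, and the same sign in 85.8% of genes. They shared 1760 higher and 1746 lower genes, and 3 genes were called in opposite directions. Both guides share the sgEV libraries. Simulated unchanged groups against shared controls gave a correlation of 0.509 and the same sign in 67.1% (mean of 20 draws). They called only 2.6 and 2.15 genes higher and 1.6 and 1.85 lower, of which 0.2 and 0.6 were shared. With so few calls the simulation cannot say how many shared genes come from the common controls. For the observed guides, independent lists would share 354 and 346 genes. The covariance was 0.347 against 0.0507 in the simulation, and part of the excess of shared genes may come from the shared controls. With a separate control library for each guide the correlation was 0.605 or 0.621. Between the guides 57 genes differed, 11 higher and 46 lower with guide 5. Lower with guide 5 were NDRG1 (-0.66 ± 0.05, adjusted p = 5.7e-05), the transcription factor IRF4 (-0.99) and the collagen hydroxylase P4HA1 (-0.41), which were chosen after their values were seen. IRF4 was not called without guide 1 library 1 (adjusted p = 0.0689) or guide 1 library 2 (0.109) and P4HA1 not without these (0.124 and 0.141), and with spike-in scaling neither NDRG1 (0.0891) nor IRF4 (0.104) nor P4HA1 (0.416) was called. Some of the 57 are near-identical copies, such as SERF1A and SERF1B, and are uncertain. The count was 9 without guide 1 library 1 or guide 1 library 2, 19 without sgEV library 1, 18 without sgEV library 2, 872 without guide 5 library 1, 365 without guide 5 library 2, 129 with the replicate number as a block and 1 with spike-in scaling. The counts of single guides fell to 2477 for guide 1 and 2360 for guide 5 without sgEV library 1 and to 2580 and 2470 without sgEV library 2. Guide 1 alone called 2773 genes without its library 1 and 2665 without its library 2.

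The overlap between the lines was tested to ask whether EZH2 depletion moved the same genes. Genes that fell in both MV4;11 and EOL-1 included the amino acid response genes ADM2 (-0.92 and -0.79) and CHAC1 (-0.98 and -0.60), the LIM protein FHL1 (-1.64 and -0.63), KANK2 (-0.60 and -0.99), TPCN1 (-0.72 and -0.71), the kinase DMPK (-0.69 and -0.79), TCTN2 (-0.60 and -0.62) and C1orf106 (-0.57 and -0.78). Genes that rose in both included PON2, LYZ (1.37 and 3.05), the coagulation factor subunit F13A1 (1.53 and 1.94), NCALD (1.86 and 1.3), ZDHHC2 (3.55 and 1.29), the adhesion molecule CADM1 (1.98 and 1.28), STOX2 (1.04 and 1.63) and UBE2E2 (1.35 in MV4;11). Of 12632 genes tested in both, 338 were lower in both against 223.6 for independent lists (Fisher's exact test, two-sided p = 4.9e-17) and 448 were higher in both against 255.7 (exact p = 3.4e-39). Genes lower in MV4;11 and higher in EOL-1 numbered 369 against 266.0 (exact p = 1.3e-12), and the reverse 221 against 215.0 (exact p = 0.638). Of 1376 genes called in both, 57.1% moved in the same direction, and the correlation across genes was 0.02. Genes are not independent, as Fisher's test assumes, and no draws matched on expression were made for this overlap. The shared lower count was 202 without shEZH2 library 1, 217 without shEZH2 library 2, 209 without sgEV library 1, 200 without sgEV library 2 and 105 with DESeq2, which gave 190 shared higher genes.

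Some of these shared genes rested on single libraries. In MV4;11, UBE2E2 was not called without shEZH2 library 2 (adjusted p = 0.0569) and DMPK not without EV library 2 (0.0804), shEZH2 library 1 (0.0760) or shEZH2 library 2 (0.164). In EOL-1, DMPK was not called without sgEV library 1 (0.104) or sgEZH2 library 1 (0.0549), TCTN2 not without sgEV library 2 (0.386) or sgEZH2 library 2 (0.147), and C1orf106 not without sgEV library 1 (0.140) or sgEZH2 library 1 (0.0945). With DESeq2 the shEZH2 calls of UBE2E2 (0.0653), STOX2 (0.0977), ADM2 (0.0592), CHAC1 (0.0770), DMPK (0.332), TCTN2 (0.144) and C1orf106 (0.0674) were lost, as were the sgEZH2 calls of ADM2 (0.0838), DMPK (0.140), TCTN2 (0.217) and C1orf106 (0.233).

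The difference between the lines was tested in one fit over 8 libraries. It passed for 3593 of 13543 genes, 1689 more positive in MV4;11 and 1904 more positive in EOL-1, and 2041 genes passed with DESeq2. Myeloid differentiation genes were more positive in EOL-1 (median difference, MV4;11 minus EOL-1, -1.36, adjusted p = 4.0e-12), as were MHC class II genes (-0.73, 1.4e-05), MHC class I genes (-0.56, 2.2e-08), interferon-stimulated genes (-0.76, 4.7e-08), granule genes (-0.71, 3.2e-07) and cholesterol synthesis genes (-0.43, 1.7e-11). Mitochondrial genome genes were more positive in MV4;11 (0.29, 5.2e-07). With an estimated correlation only cholesterol synthesis passed (adjusted p = 0.0399), and the myeloid, MHC class II and interferon lists were at 0.0586 each. The line, the depletion method and the depth differ together between these comparisons, and each table was made separately.

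The series title joins EZH2 and cMyc in gene activation, so genes that fell after either was targeted in MV4;11 were compared. Lower in both were the glycine transporter SLC6A9 (-2.20 with shEZH2 and -3.93 with sgcMyc), the glutamine transporter SLC38A1 (-2.14 and -1.93), the adhesion molecule NCAM1 (-1.92 and -1.89), the chemokine CCL5 (-1.77 and -2.11), FHL1 (-1.64 and -2.37), the receptor kinase AXL (-1.63 and -1.95), OCSTAMP (-1.54 and -1.74) and SLCO4C1 (-1.93 and -1.34). Higher in both were LYZ, F13A1 (1.53 and 3.03), BST1 (1.47 and 2.33), SESN3 (1.78 and 1.32), SLC43A2 (1.46 and 1.31), CHST2 (1.71 and 1.2), ACSM3 (1.21 and 1.1) and SULT1B1 (1.12 and 2.80). The SULT1B1 call in shEZH2 was lost without shEZH2 library 1 (adjusted p = 0.0552) and with DESeq2 (0.0503). Of 13230 genes tested in both, 592 were lower in both against 359.2 for independent lists (Fisher's exact test, two-sided p = 2.6e-44) and 454 higher in both against 337.0 (exact p = 1.7e-13). Opposite directions were also more frequent than for independent lists, with 477 genes lower with shEZH2 and higher with sgcMyc against 360.8 (exact p = 1.0e-12) and 399 the reverse against 335.5 (exact p = 5.3e-05). Of 1922 genes called in both, 54.4% moved in the same direction, and the correlation across genes was 0.12. DESeq2 gave 278 shared lower and 226 shared higher genes, and spike-in scaling gave 300 and 259. These comparisons have different control libraries, and Fisher's test takes genes as independent, which they are not.

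**Figure D4:**
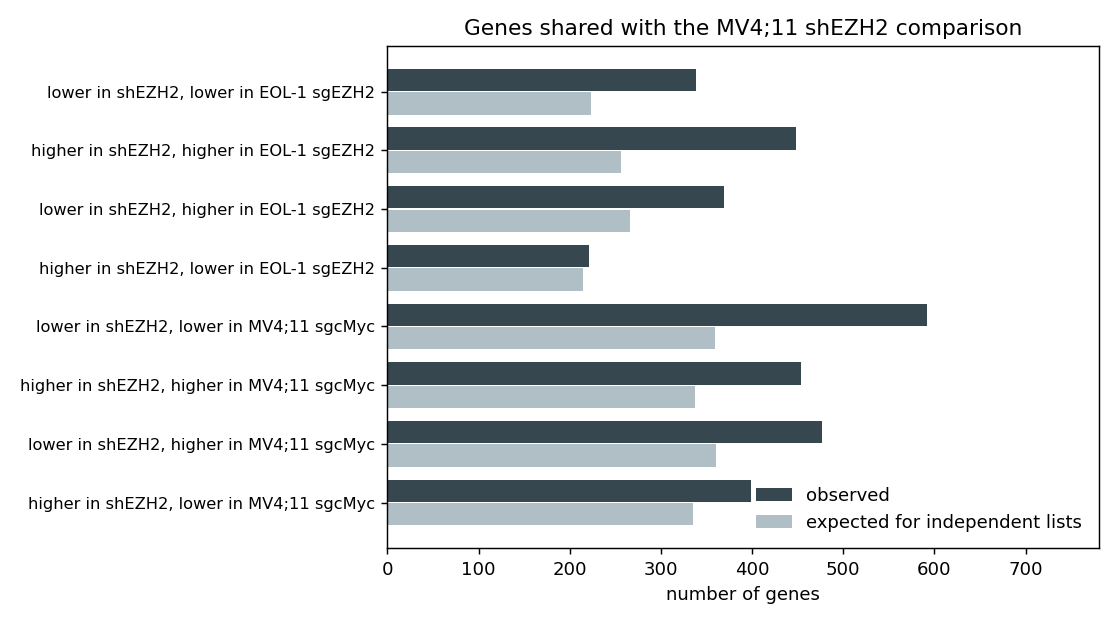
Number of genes called in shEZH2 against EV and in a second comparison (horizontal axis, dark bars), beside the number expected for independent lists (light bars), for each pair of directions. The 592 genes lower in both shEZH2 and sgcMyc stand beside an expected 359.2, and the 338 genes lower in both lines beside 223.6.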

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

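The tests chosen only after the result was seen are the comparison of the EZH2 transcript between lines, the count of libraries with the other depletion method, and the 3 tests of the amino acid genes.

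Myeloid and MHC genes rose with EZH2 depletion in EOL-1, and the difference from MV4;11 passed the interaction test, with median differences of -1.36 for myeloid differentiation, -0.56 for MHC class I and -0.73 for MHC class II, calls that were lost with an estimated correlation (adjusted p = 0.0586, 0.0870 and 0.0586). Deeper sequencing of EOL-1 is argued against as the source of most of these calls. Of the 55 members called higher, 45 (81.82%) were still called after EOL-1 counts were thinned to the MV4;11 depth. These members were picked from the same counts. Over all genes 1702 were higher after thinning, against 2099 before, so keeping the call is not particular to them. Of the 55 members 11 were higher and 19 lower in MV4;11, where some, such as HLA-DPA1 and S100A9, were not tested. A larger fall of the EZH2 transcript in EOL-1 is argued against as well, since the EZH2 difference was -1.542, a deeper fall in MV4;11, but the transcript does not measure depletion by an sgRNA, so a larger loss of EZH2 protein in EOL-1 stays open. The line and the depletion method (shRNA against sgRNA) cannot be told apart, because 0 libraries have the other method in the same line. A difference between the lines in the genes that EZH2 holds low is consistent with these values, as is an effect of one hairpin or one guide on other targets, and neither was tested.

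Amino acid and ER stress genes were lower in the libraries labelled sgcMyc by a median of -1.40. Scaling of the libraries is argued against, because the median was -1.287 with spike-in scaling. An off-target effect of 1 guide is argued against, because the less negative of the guides' medians was -1.4, and a single mislabelled or swapped library too, since 0 libraries labelled sgcMyc reached the list mean of a library labelled sgEV (5.68 to 5.75 against 7.09 and 7.10 on the log2 CPM scale). The medians of both guides were taken against the same sgEV libraries, so they are not independent of each other. An exchange of whole groups stays open, and so does amino acid supply or medium age in the cultures, which could move the same genes. A fall that follows from loss of MYC may be the biological explanation, but the MYC transcript was not lower, so the tables hold no direct measure of the knockout. The MYC-activated genes did not pass as a set in these libraries, as given above, so they give this explanation no backing.

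More genes were lower after both shEZH2 and sgcMyc than independent lists would share (592 against 359.2). A bias towards highly expressed genes is argued against, because the highest of 1000 draws matched on mean expression gave 439 (mean 390), although genes lower with shEZH2 and higher with sgcMyc also exceeded their draws (477 against a highest of 474). Scaling of the libraries is argued against too, because the ratio to independent lists was 2.679 with spike-in scaling (300 against 112 genes). Opposite directions exceeded independent lists as well (477 against 360.8 and 399 against 335.5), but genes higher with shEZH2 and lower with sgcMyc stayed within their matched draws (399 against a highest of 419, with 51 of 1000 as large). It stays open whether some genes are called more readily in both comparisons, as do a shared response of stressed cells and a common set of genes activated by EZH2 and cMyc, and none of these was tested.

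The remaining values are differences of the log2 fold change, MV4;11 minus EOL-1, that passed the interaction test for a difference between the lines, which held for 3593 genes. Of 114 named genes compared, 85 differed, against 3593 of all 13543 genes. Most of the named genes were picked for large changes or small p in these same libraries. That choice raises their share, so it shows no excess over other genes. Of 28 lists 16 differed, 1 of them with an estimated correlation. For PON2 (5.74), UBE2E2 (-5.68), IGF2BP2 (-6.55), IGF1 (-7.83) and S100A9 (-3.20) a group held 0 to 3 counts, so these fitted values depend on the prior count. EZH2 differed by -1.54 and MYC by 0.30.

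Among the genes with the largest changes, the differences were 3.03 for HUNK, 3.66 for NT5C3B, 2.27 for ZDHHC2, 3.51 for CYFIP2, 3.30 for HAPLN4, -7.89 for MYBPH, -3.20 for ZNF71, -4.80 for LGALS3BP, -6.92 for CHI3L1 and -3.50 for FCER2. They were -3.99 for NEDD4, 2.21 for the readthrough symbol TMEM110-MUSTN1, 1.08 for PHACTR3 and -2.18 for GNG4. HLA-DPA1 (-4.50, SE 1.02) and DSC2 (-3.64) differed too, and these genes, like S100A9, had too few counts to be tested within the MV4;11 comparison. For genes called in the same direction in both lines they were -1.67 for LYZ, 0.56 for NCALD, 0.72 for CADM1, -1.0 for FHL1 and 0.40 for KANK2.

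In the myeloid, granule and MHC lists the differences were -3.06 for CD36, -3.63 for CSF1R, -2.54 for FCGR1A, -1.23 for CTSB, -2.85 for PRTN3, -2.20 for MPO, -2.12 for MS4A3, -1.0 for CFD and 0.87 for IGLL1. They were -3.35 for HLA-DRB1, -1.10 for HLA-C and -1.19 for HLA-B. Interferon-stimulated genes gave -2.75 for DDX60, -3.43 for GBP2, -0.62 for BST2, -0.40 for XAF1, -0.99 for PARP14 and 0.48 for TRIM22. In the HOXA-MEIS1 and Polycomb lists the values were -2.39 for MEF2C, -0.62 for FLT3, -1.52 for SATB1, -0.62 for BMI1, 0.36 for CDK6 and 0.72 for JARID2.

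Cholesterol genes gave -1.15 for CYP51A1 and -0.56 for SREBF2. Cell cycle genes gave -0.87 for CDC20, -0.44 for ANLN, -0.39 for BIRC5, -0.23 for CCNB1, -0.21 for UHRF1, -0.25 for MCM3, 0.38 for POLE, 0.27 for CDC6, 0.21 for CDT1 and 0.15 for MCM4. Amino acid and ER stress genes gave -0.38 for PSAT1, -0.82 for PHGDH, -0.76 for ASNS, -0.43 for TRIB3, 0.52 for SLC7A5, -0.44 for HERPUD1 and -0.35 for HSPA5. The p53 targets gave 0.53 for RRM2B, 0.33 for SESN1 and -1.59 for CDKN1A. Other values were 0.19 for RPL5, 0.16 for RPL15, 0.36 for MT-CYB, 0.17 for MT-ND2, 0.39 for BCL2, -0.30 for JUND, 0.49 for UTP20, 0.26 for CAD, -0.20 for YARS, 0.23 for UNG and -1.13 for KRT8.

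Median differences of the other lists that passed were -0.43 for cholesterol synthesis, -0.76 for interferon-stimulated genes, -0.71 for granule genes, 0.29 for the mitochondrial genome, 0.08 for ribosomal proteins and 0.06 for MYC-activated genes. With an estimated correlation only cholesterol synthesis kept its call (adjusted p = 0.0399), and every other list in this paragraph lost it, from 0.0586 for interferon-stimulated genes to 0.805 for ribosomal proteins. The others were -0.12 for the HOXA-MEIS1 programme, 0.08 for rRNA synthesis and ribosome assembly, -0.13 for the amino acid and ER stress list, 0.12 for p53 targets, -0.30 for CDK inhibitors, 0.13 for PRC2 and 0.16 for nucleotide synthesis.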

How the results depend on the processing

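The spike-in scaling, the limma test on the authors' log2 values and all alternatives of the difference between the lines were chosen after seeing the data. Of 6359 alternative values for 470 single-gene results, 6145 kept direction and side of the threshold, 199 lost the call, 15 gained one and 0 reversed. Of 1061 for 84 gene list results, 967 were unchanged in this sense, 65 lost the call (40 of them with an estimated correlation), 28 gained one and 1 reversed: the BCL2 family in sgcMyc had an upward camera direction that was not called, and fry called it downward (mean -0.0586, adjusted p = 0.0145), and the cause was not tested. With fry the calls were also lost for cytosolic ribosomal proteins in shEZH2 (adjusted p = 0.197), EOL-1 (0.284) and sgcMyc (0.0643), for granule genes (0.0685) and immediate early genes (0.116) in shEZH2, for MYC-activated genes (0.126) and the mitochondrial genome (0.0808) in EOL-1 and for nuclear-encoded oxidative phosphorylation in sgcMyc (0.152). Of 239 for 14 counts, 171 stayed within 1.5 times and 68 moved. DESeq2 called 905 higher and 939 lower for shEZH2, 1122 and 748 for EOL-1, 1635 and 1584 for sgcMyc, 2624 for guide 1 and 2547 for guide 5. It gave 105 shared lower and 190 shared higher genes between the lines, 278 and 226 between shEZH2 and sgcMyc, and 2041 genes that differ between lines. The cause was not tested. With spike-in scaling there were 805 higher for shEZH2, 1169 lower for sgcMyc, 1 gene between the guides, and 300 lower and 259 higher shared between shEZH2 and sgcMyc, and this scaling moved the median of all tested genes to -0.0443 for shEZH2 and to 0.113 for sgcMyc. Stricter thresholds call fewer genes by construction. With an absolute log2 fold change of at least 1 there were 244 and 290 for shEZH2, 466 and 52 for EOL-1, 261 and 401 for sgcMyc, 651 for guide 1, 606 for guide 5, 14 between guides, 6 and 24 shared between lines (lower and higher), 64 and 21 shared between shEZH2 and sgcMyc and 759 differing between lines. With adjusted p under 0.01 there were 1030 and 1132 for shEZH2, 936 lower for EOL-1, 1719 higher for sgcMyc, 2858 for guide 1, 2762 for guide 5, 16 between guides, 133 and 228 shared between lines, 316 and 260 shared between shEZH2 and sgcMyc and 2198 differing between lines. The replicate numbers are only shared, not a stated pairing: deviations of same-numbered libraries correlated at 0.192 for shEZH2, at 0.0419, 0.0551 and 0.195 in the sgcMyc table and at 0.0395 in EOL-1. With the replicate block 129 genes differed between the guides, and the 12 other counts run with it stayed within 1.5 times, while the difference between the lines was not run with the block. Leaving out each library in turn, where the lone library is assumed to vary like the others, gave 1186 to 2200 higher and 1290 to 2072 lower for shEZH2, 1569 to 2022 and 1020 to 1942 for EOL-1 and 1427 to 3094 and 1502 to 3082 for sgcMyc. Moves of over 1.5 times came without shEZH2 library 1 (1186 higher), without sgEV library 1 or 2 of EOL-1 (1061 and 1020 lower) and without sgEV library 1 or 2 of the sgcMyc table (1427 and 1511 higher, 1508 and 1502 lower). The ranges were 2477 to 5758 for guide 1, 2360 to 5076 for guide 5 and 9 to 872 between the guides. Without sgEV library 1 or 2 these were 2477 and 2580 for guide 1, 2360 and 2470 for guide 5 and 19 and 18 between the guides, without guide 1 library 1 or 2 they were 2773 and 2665 for guide 1 and 9 and 9 between the guides, and without guide 5 library 1 or 2 there were 872 and 365 between the guides. The cause was not tested. The ranges were 200 to 409 lower and 315 to 488 higher shared between lines, 417 to 649 and 320 to 537 shared between shEZH2 and sgcMyc, and 2667 to 3622 differing between lines. Of the shared lower genes of the lines there were 202 without shEZH2 library 1, 217 without shEZH2 library 2, 209 without sgEV library 1 of EOL-1 and 200 without sgEV library 2. EZH2 stayed between -2.96 and -2.91 with shEZH2 and between -1.44 and -1.35 in EOL-1, and MYC at 0.36 in sgcMyc, at 0.39 to 0.40 with guide 1 and at 0.31 to 0.32 with guide 5. The planned pseudocount of 5 applies to normalised values only and was not run. Genes with few counts limit the folds of PON2, UBE2E2, PTPN13, IGF2BP2 and S100A9, and 2 libraries per group limit what the spread can show.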

Other observations

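The overlap of EOL-1 with sgcMyc and the tests of the hypoxia-type genes were chosen only after the result was seen, and the test of genes switched on or off was fixed before it.

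EOL-1 with sgEZH2 and the MV4;11 libraries labelled sgcMyc shared more changes in the same direction than independent lists would. Of 12709 genes tested in both, 701 were higher in both against 375.0 for independent lists (Fisher's exact test, two-sided p = 3.3e-81) and 472 lower in both against 296.4 (exact p = 1.8e-30). Genes lower in EOL-1 and higher in sgcMyc were fewer than for independent lists (239 against 304.4, exact p = 5.6e-06), and the reverse did not differ by the test (392 against 365.2, exact p = 0.0945). Of 1804 genes called in both 65.0% moved in the same direction, and the correlation across genes was 0.166. Here too genes are not independent, as Fisher's test assumes, and no draws matched on expression were made. Myeloid genes that stood higher in both included LYZ (3.05 and 4.50), CD36 (2.69 and 1.78) and MS4A3 of the granule list (3.07 and 2.46). HLA-DRA (1.28 and 1.52) and HLA-B (1.27 and 0.79) stood higher in both as well. With an estimated correlation camera no longer called the myeloid differentiation list in EOL-1 (adjusted p = 0.1755) or in sgcMyc (adjusted p = 0.06685). Interferon-stimulated genes had a median of 0.24 in EOL-1 and -0.41 in sgcMyc, with LGALS3BP at 1.49 and -0.92. The difference of these effects was not tested, since the lines and targets differ together.

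A hypothesis that loss of EZH2 raises transcripts of silent genes was tested in both lines. It asked that genes under 0.5 CPM in the controls and over 2 CPM after depletion outnumber the reverse by at least 2 to 1 in each line. In MV4;11 7 genes were switched on and 12 off (exact binomial p = 0.359), and in EOL-1 24 were switched on and 3 off (exact binomial p = 4.9e-05). The binomial test counts genes as independent, which co-regulated genes are not, so its p-values do not measure the spread between libraries. The smaller ratio was 0.5833, so the hypothesis was not met in MV4;11 among the genes deposited for it. Only 56 of 15025 gene rows for shEZH2 and 27 of 15031 for EOL-1 were at 0 in every library. Any gene filter of the authors is not stated, so silent genes may be missing, and these counts cannot speak for them. Those switched on in EOL-1 included IGF1, NEDD4, DSC2, SPRED1 and MNDA (3.63). In the libraries labelled sgcMyc 14 genes were switched on and 9 off (exact binomial p = 0.405).

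The genes that differed between the guides included NDRG1, a gene induced by low oxygen, which was not called with spike-in scaling. As a hypothesis, the guide 5 libraries may carry a lower hypoxia-type programme than the guide 1 libraries. A typed list of such genes, without the members already seen, had a median difference of -0.1383 (guide 5 minus guide 1), with 20 of 26 tested members below 0 and 1 called lower. For this difference camera of limma gave p = 1.8e-09 with the preset correlation and p = 0.0128 with an estimated one. The list was also lower than sgEV with each guide, with a median of -0.203 for guide 1 (10 lower, 2 higher) and of -0.271 for guide 5 (14 lower, 0 higher), so a fall of these genes is no trait of the guide 5 libraries alone. The values go with the hypothesis, but it was formed on the same libraries. The tested members may also move together with those already seen, so this is no independent test. Culture density or time at harvest could move such genes, and no label records either.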
